A study of Mus musculus with 4 samples.

How the data were processed

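The series measured chromatin accessibility by ATAC-seq in wild-type and Chd7-knockout G1ER cells of the mouse, with 2 libraries per genotype and 50000 cells per library. Per the labels' protocols, lysates were treated with Nextera transposase for 1 to 2 h at 37C, and indexed libraries were sequenced on an Illumina HiSeq instrument. Groups and replicate numbers came from the sample titles. Replicate 1 of each genotype was labelled 1 h and replicate 2 was labelled 2 h.

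The files were 1 peak list per library. Bowtie2 2.2.1 and MACS2 2.1.0 are named in the submitters' processing notes, with no role or order, together with several genome builds. The deposited peak names give GRCm38, and all positions are on that build, printed from base 1. The lists were called per library. The calling threshold, any control, the shift of reads for the transposase cut, duplicate removal and blacklist filtering are not given in the sources used here. Each deposited list holds a score per peak, which is about 10 times the deposited −log10 q value, as a whole number. The deposited fold enrichment is the ratio of fragment pileup to local background at the summit as the authors' caller gave it. The −log10 p and −log10 q values are likewise the authors' own. The smallest deposited −log10 q was between 1.32 and 1.42 in the 4 lists. Score, fold enrichment and −log10 q describe a peak within its own list and were used here to rank or filter within that list.

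Peaks on chromosomes 1 to 19, X and Y were used, and 2 mitochondrial peaks per library were left out. Fold enrichment, taken as pileup plus 1 over background plus 1, and the Poisson p-value together determine the whole-number pileup and the background at each summit. This recovered 99.99% of peaks in each library, 1 peak per library excepted, with a tolerance of 0.001 in −log10 p. Comparing recovered pileups between libraries assumes that the caller did not rescale them. The lowest background of each library was used as relative depth, which assumes the same read extension in each library. Total reads were unknown, so intervals printed for shares cover counting of regions only.

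Peaks of the 4 libraries were merged into union regions wherever they overlapped or touched, and bedtools 2.31.1 merge gave the same 15328 regions. A region counted as called in a library if any of its peaks fell in it. The strength of a region was the percentile of its fold enrichment in its own list, taking the lower of the libraries compared. Genes were taken from a GRCm38.p6 RefSeq gene table with gene starts and ends. Since that table holds no strand, exons or transcripts, transcription start sites were replaced by both ends of each protein-coding gene: gene edge means overlap with 1 kb either side of an end, and a region was linked to the gene with the nearest end within 100 kb of its middle. The 12 gene lists, the naming rule, the main tests of the report and most alternative settings were fixed before the data were examined. Of their genes, Ahsp and Tpsab1 had no protein-coding entry in the table. The 10 motif tests that had been planned, with their window and GC alternatives, were not run because no genome sequence was used here.

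Named regions were the 10 strongest of each class with a linked gene, the 5 strongest of each class at a gene edge, up to 4 genes of each list by strength, and Chd7, Runx1, Gata1, Gata2 and Kit. Fech, Cish, Spred1, Spred2 and Ldb1 lie outside this rule and were added to complete small groups after their values were seen.

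Values per library were compared by exact two-sided permutation tests over the 6 assignments of the labels, whose smallest p is 0.333. Shares of regions were compared by two-sided Fisher's exact tests with Woolf intervals on the odds ratio. List tests used regions called in at least 2 libraries as background, with Benjamini-Hochberg adjustment over the 24 tests. The chromosome test used the chi-square statistic with 100000 permutations of the class over regions, with adjustment over 20 chromosomes. All tests over regions describe these 4 libraries. The alternatives were lists of equal length, a −log10 q of at least 5, that threshold applied to the calling genotype alone, windows of 250 bp either side of summits, 500 bp gene edges, links within 50 kb, the replicate block and each library left out. Added after the data were seen were genes taken by span, equal-width windows, ends of long non-coding genes and, for pileups, the limma comparison, the shift between gene-edge and other regions and the list medians. In the closing section, log2 of recovered pileup plus 1, centred on each library's median, was compared with limma 3.58.1 in R 4.3.3 over 8704 regions, those of the 8705 called in all 4 libraries whose pileup was recovered in each. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

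These steps were tested on simulated data. Pileups were recovered exactly for 99.9% of 5000 simulated peaks. Of 1000 simulated comparisons of gene-edge shares without a difference, 4.2% passed the threshold. The chromosome test passed in 6% of 200 simulations without a difference and in 67.5% with 1 chromosome at 3 times its share. Permuted within gene-edge and other regions, it passed in 5% of 200 simulations of classes that differed through the gene-edge share alone. The bootstrap interval held the known gap in 95% of 200 simulations, and the test against random sets passed in 2% of 200 without a shift. For the genotype comparison of pileups, limma recovered 45.5% of 200 regions changed 2-fold with 1 false call, and 94% of 200 regions changed 3-fold with 9 false calls, among 8704 regions.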

Results

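Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in the mouse erythroblast line G1ER and in G1ER cells lacking Chd7. G1ER cells descend from Gata1-null cells and carry GATA1 fused to an estrogen receptor domain. CHD7 is a chromodomain helicase that remodels nucleosomes. The series asks what loss of CHD7 does to chromatin accessibility in these cells, and its title names an interaction of CHD7 with Runx1, a transcription factor of blood formation. There were 4 libraries of 50000 cells each: 2 of wild-type cells (replicate 1 labelled 1 h, replicate 2 labelled 2 h) and 2 of knockout cells with the same labelled times. The labels describe no treatment, and the range of times matches that given for transposition. Nothing in the labels says whether replicates were separate cultures, so the spread between them may be technical. Both knockout libraries carry the same code in their descriptions, and genotype was not separable from clone.

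The deposited lists held 11084 and 12043 nuclear peaks in wild-type replicates 1 and 2, and 12443 and 11376 in knockout replicates 1 and 2. Total read depth was unknown. The lowest background density behind the peaks, which scales with depth if the caller extended reads alike in each library, was 0.787 and 1.08 fragments per base in the wild-type libraries and 1.04 and 1.01 in the knockout libraries, so wild-type replicate 1 had the lowest value, at 73.0% of the highest. The median peak summit held 19, 22, 20 and 19 fragments, in the same order. Strong peaks recurred far more often than weak ones: of the strongest 25% of regions in each library, between 99.8% and 99.9% were called in all 4 libraries, against 28.5% to 44.1% of the weakest 25%.

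Chd7 itself, on chromosome 4 from 8690402 to 8868449 (GRCm38), had 0 peaks within its span or linked to it in any of the 4 libraries, so the lists give no check of the genotype labels. Runx1, on chromosome 16 from 92601466 to 92826074, held 9 regions in its span, of which 3 were called in all 4 libraries, 3 in exactly 3 and 3 in 1. None of them was specific to a genotype. The strongest, at 92715517 to 92716214, had fold enrichments of 10.7 and 10.4 in wild-type replicates 1 and 2 and of 14.1 and 9.88 in knockout replicates 1 and 2. A region at the edge of Runx1 (92825901 to 92826324) was called in all libraries except wild-type replicate 2. At Kit, the stem cell factor receptor, the region over the gene end on chromosome 5 (75574657 to 75575115) was called in all 4 libraries, with fold enrichments of 10.3 and 7.66 in wild type and 6.15 and 4.58 in knockout. These enrichments are the authors' own values from separately called lists and were not tested against each other. In the limma comparison of recovered pileups, described below, neither region passed, with adjusted p = 0.491 for the Runx1 region and 0.458 for the Kit region. Gata1 had 1 region, called in all 4 libraries (chromosome X, 7964087 to 7964422). Gata2 had 2 linked regions, 1 called in 3 libraries and 1 in wild-type replicate 2 alone.

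The 4 lists merged into 15328 regions. Most of the strong accessible landscape was shared: 8705 regions (56.8%) were called in all 4 libraries, and 3322 in 1 library. Called in both knockout libraries and neither wild-type library were 415 regions, termed knockout-only. Called in both wild-type libraries and neither knockout library were 345 regions, termed wild-type-only. The genotype split thus gave 760 exclusive regions. Which class was larger depended on the setting: with lists of equal length there were 364 knockout-only and 388 wild-type-only regions, and with −log10 q of at least 5 in every library 283 and 387. Both settings drop weaker peaks before classes are formed, so an exclusive region could then hold a dropped peak of the other genotype. Splitting the same libraries by labelled time gave 458 (213 for 1 h and 245 for 2 h), and the crossed split gave 507 (391 and 116). With 3 possible splits no test across libraries could pass 0.05. Requiring −log10 q of at least 5 in both libraries of the calling genotype left 151 knockout-only and 158 wild-type-only regions. Leaving out 1 library, which removes a required call or a required absence, gave 638 to 1651 and 617 to 1208.

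**Figure D1:**
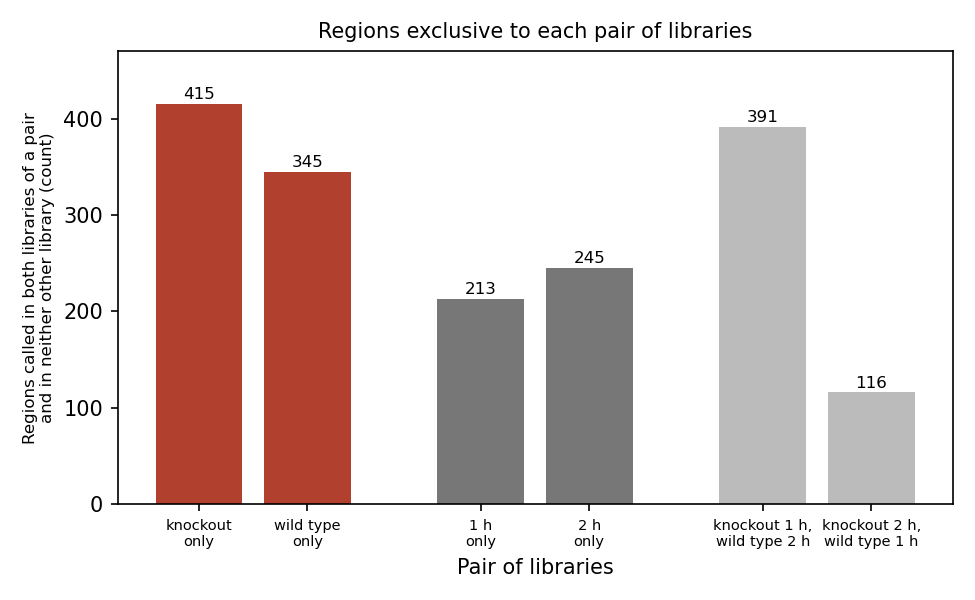
Number of merged regions (vertical axis, count) called in both libraries of a pair and in neither of the other libraries, for each of the 6 pairs on the horizontal axis, 1 bar per pair. The genotype pairs gave 415 and 345 regions, the time pairs 213 and 245, and the crossed pairs 391 and 116.

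The base-pair overlap of whole lists differed little between pairs. The Jaccard index was 0.670 between the wild-type libraries and 0.643 between the knockout libraries. Pairs of different genotype ranged from 0.638 to 0.645, so 1 of them exceeded the knockout pair. The mean within genotypes was 0.0162 above that between genotypes. The same difference was −0.011 for the split by labelled time and −0.00517 for the crossed split.

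The 2 exclusive classes differed in where they lay relative to genes. Knockout-only regions lay mostly away from gene ends: 81 of 415 (19.5%, 95% exact interval 15.8 to 23.7) overlapped the 1 kb either side of a protein-coding gene end, termed gene edge, and 42.2% lay outside genes. Of the wild-type-only regions, 137 of 345 (39.7%, 34.5 to 45.1) were at a gene edge and 27.8% lay outside genes. The median distance to a gene end was 13.3 kb for knockout-only and 3.61 kb for wild-type-only regions. The odds ratio of the gene-edge share was 0.368 (95% interval 0.266 to 0.509; two-sided Fisher's exact p = 1.16e-09), which compares regions of these 4 libraries and not replicates. Regions called in exactly 1 library of each genotype, which have the same number of calls, lay between the classes at 29.7%. Knockout-only regions fell below them (odds ratio 0.573, Fisher's exact p = 6.69e-05), and wild-type-only regions lay above them (odds ratio 1.56, Fisher's exact p = 7.98e-04). Regions called in all 4 libraries were at a gene edge in 68.4% of cases.

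The odds ratio was below 1 within each labelled time. For regions called in 1 library alone, knockout against wild type, the odds ratio was 0.575 at 1 h and 0.690 at 2 h. These regions are in neither exclusive class but come from the same libraries. At 1 h, regions called in knockout but not wild type against the converse gave an odds ratio of 0.515 (Fisher's exact p = 5.04e-18), and at 2 h of 0.569 (p = 1.94e-13 by the same test). The comparisons that gave 0.515 and 0.569 contain the knockout-only and wild-type-only regions, so they are not separate from the result above. In the split by labelled time the odds ratio was 0.931 (Fisher's exact p = 0.759), and in the crossed split 0.609 (0.393 to 0.942; Fisher's exact p = 0.0280). Without wild-type replicate 1 the genotype odds ratio was 0.621, and without wild-type replicate 2 it was 0.758, both still past the threshold. Per library, the share of all peaks at a gene edge was 60.1% ± 1.78 (SD, n = 2) in wild type and 57.3% ± 2.07 (SD, n = 2) in knockout, exact permutation p = 0.333, and the knockout share differed by −5.52 percentage points at 1 h and by −0.0819 at 2 h. When every list was reduced to its strongest 11084 peaks, 61.4% ± 0.0510 (SD, n = 2) of wild-type peaks and 59.4% ± 0.198 (SD, n = 2) of knockout peaks were at a gene edge, exact permutation p = 0.333. The differences were then −2.18 and −1.83 percentage points at 1 h and 2 h. A p of 0.333 is the smallest two-sided p that 2 libraries against 2 can give.

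**Figure D2:**
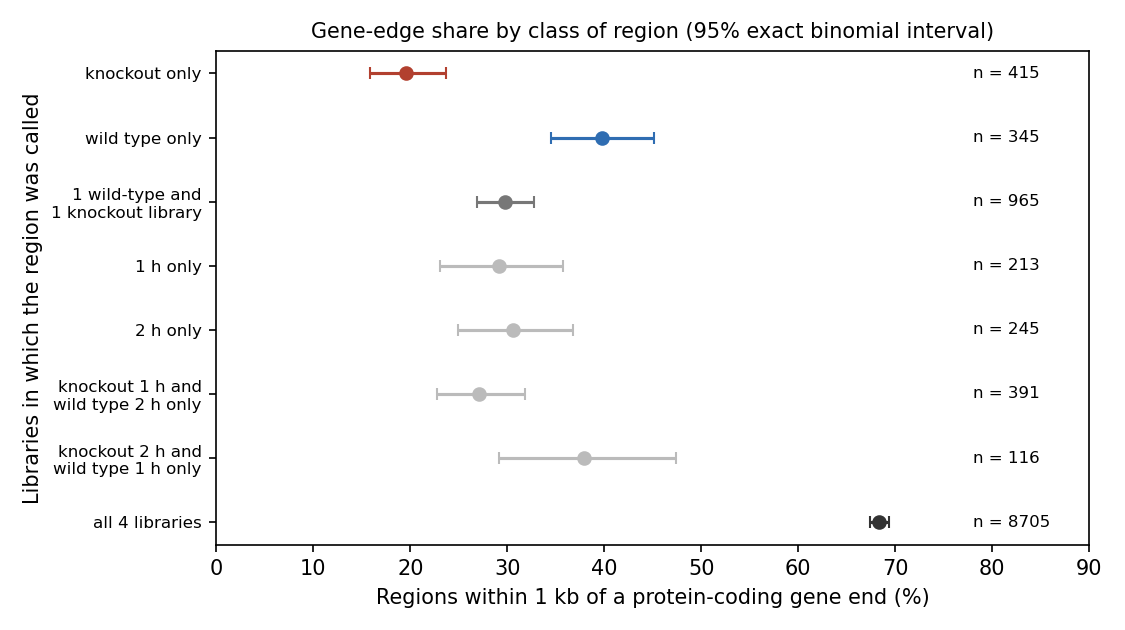
Share of regions within 1 kb of a protein-coding gene end (horizontal axis, percent) for each class of regions by the libraries in which they were called (vertical axis). Points are shares, bars are 95% exact binomial intervals over regions, and n is the number of regions. Knockout-only regions lie at 19.5% and wild-type-only regions at 39.7%, with the mixed class at 29.7% and regions called in all 4 libraries at 68.4%.

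Among knockout-only regions with a gene end within 100 kb, the strongest lay at the edge of Vbp1, which encodes a prefoldin subunit (chromosome X, 75514072 to 75514463), with fold enrichments of 9.82 at 1 h and 9.95 at 2 h. It was followed by a region inside Lrrfip2 (chromosome 9, 111152328 to 111152812; 9.77 and 11.2) and one inside Atp8b1, a phospholipid flippase gene (chromosome 18, 64578297 to 64578914; 8.61 and 8.26). The remaining 7 of these 10 were linked to Chrna3, a nicotinic receptor subunit gene, Slc35g1, Dbndd2, Cpeb4, a regulator of translation, Gm46345, Lrrc6 and Zfyve16. Of these 7, the one linked to Dbndd2 was at a gene edge. The next knockout-only regions at gene edges belonged to Ccno, Ebp, a sterol isomerase gene of cholesterol synthesis, and Zfp239. Of the knockout-only regions with no gene end that near, 1 on chromosome 18 (29673843 to 29674286, strength percentile 73.5) exceeded the region at Vbp1 (71.4), and others on chromosome 15 (19622234 to 19622737, 64.7) and chromosome 3 (8022644 to 8023128, 51.4) ranked above several of the 10.

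Among wild-type-only regions with a linked gene, the strongest lay at the edge of Erich1 (chromosome 8, 14090080 to 14090668), with fold enrichments of 11.98 at 1 h and 10.3 at 2 h. A region 10798 bp from Trim43c (chromosome 9, 88858713 to 88859263) had 10.3 and 9.59, and one 8029 bp from Ets2, an ETS-family transcription factor gene (chromosome 16, 95728811 to 95729345), had 7.65 and 7.66. The others of the 10 strongest linked regions belonged to Wipi1, an autophagy gene, Fcgr3, an Fc receptor gene of myeloid cells, Iqcc, Lmnb1, which encodes lamin B1, Zfp608, Ttc25 and Cdca7. Regions at Iqcc, Ttc25, Cdca7 and Tmem35b were at a gene edge. Both classes were made mainly of weak peaks: 10 knockout-only and 2 wild-type-only regions ranked above the middle of both their own lists by fold enrichment.

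Genes of the erythroid programme had exclusive regions of both kinds. Knockout-only regions were linked to Kel, the Kell blood group gene, Car1, a carbonic anhydrase gene, and Fech, the last enzyme of haem synthesis. Wild-type-only regions were linked to Epb42 and Add2, genes of the red cell membrane skeleton. The Epb42 region was at the gene edge (chromosome 2, 121036718 to 121037250) with fold enrichments of 5.60 and 6.26, and the Car1 region likewise (chromosome 3, 14808342 to 14808711) with 5.61 and 4.76. Neither class passed the test for this list, and the intervals were wide. The odds ratio was 2.05 for knockout-only (0.633 to 6.65; Fisher's exact p = 0.194) and 1.61 for wild-type-only regions (0.389 to 6.69; Fisher's exact p = 0.362). Without wild-type replicate 2 these odds ratios were 0.852 and 0.961. The regions at Epb42, Car1 and Kel left their classes under both stricter thresholds, −log10 q of at least 5 in every library or in the calling genotype alone.

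Genes of cytokine signalling and survival were linked to 5 of 345 wild-type-only regions, at Cish, Jak2, the kinase bound to the erythropoietin receptor, Pim1, Spred2 and Spry1. The odds ratio against other regions called in at least 2 libraries was 4.07 (1.60 to 10.4), with Fisher's exact p = 0.0109 and adjusted p = 0.261 over the 24 tests, so the list did not pass. The odds ratio was 1.41 and 2.01 without wild-type replicates 1 and 2. It was 2.32 and 3.56 without knockout replicates 1 and 2, and 2.15 with lists of equal length. The regions at Cish, Jak2 and Spred2 left their class under both stricter thresholds. With −log10 q of at least 5 in the calling genotype alone, the 2 wild-type-only regions of this list that remained were at Pim1 and Spry1. Knockout-only regions of this list were linked to Irs2 and Spred1, and the one at Spred1 left its class under both stricter thresholds. Among haematopoietic transcription factors and cofactors, Elf1, Klf6 and Tcf12 had knockout-only regions, and Sox6, Myb and Ldb1 had wild-type-only regions (odds ratios 1.04 and 1.25, the latter 0.776 without wild-type replicate 2). With lists of equal length, 6 regions of each class were linked to this list (odds ratios 2.53 and 2.36, adjusted p = 0.410 for both by Fisher's exact test). The regions at Tcf12, Myb and Ldb1 left their classes under both stricter thresholds. When peaks needed −log10 q of at least 5 in every library, 8 knockout-only regions were linked to this list (odds ratio 4.79, adjusted p = 0.0130 by Fisher's exact test). So were 6 wild-type-only regions (odds ratio 2.49, adjusted p = 0.373 by the same exact test). Regions of either class could then hold a weaker called peak in the other genotype. With that threshold on the calling genotype alone, and no called peak in wild type, 2 knockout-only regions were linked to it (odds ratio 1.93, Fisher's exact p = 0.285). Of the remodellers, Chd2 and Chd9, relatives of Chd7, were linked to 3 knockout-only regions and Atrx to 1 wild-type-only region. Under both stricter thresholds 0 regions of either class were linked to this list of remodellers. With lists of equal length it had 1 knockout-only and 2 wild-type-only regions.

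Few regions of any kind were linked to markers of other blood lineages, between 3 and 27 per list among the regions called in at least 2 libraries. Granulocyte and macrophage genes had 2 wild-type-only regions, at Cebpb and Fcgr3 (odds ratio 5.22, Fisher's exact p = 0.0676, adjusted p = 0.811), and 0 knockout-only regions. The odds ratio was 3.77 and 3.21 without wild-type replicates 1 and 2, and 3.72 and 2.53 without knockout replicates 1 and 2. With lists of equal length it was 7.82 (adjusted p = 0.256 by Fisher's exact test). Megakaryocyte genes had 1 region of each class, at Rab27b in knockout and Mmrn1 in wild type. The mast cell list had 1 knockout-only region, at Cpa3, and the stem and progenitor list 1 wild-type-only region, at Myb. Cell cycle genes had a knockout-only region at Cdk6 and a wild-type-only region at E2f3, and housekeeping genes a knockout-only region at Ywhaz. Of the regions in this paragraph, those at Cebpb, Mmrn1, Cpa3, Myb, Cdk6 and Ywhaz left their classes under both stricter thresholds. Lymphoid genes and developmental genes linked to CHD7 in the neural crest had 0 regions in both classes. Over the 12 lists and both classes, 0 of 24 Fisher's exact tests passed after Benjamini-Hochberg adjustment and 1 had an unadjusted p below 0.05.

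The classes spread differently over the chromosomes (permutation test with 100000 permutations of the class over regions, p = 0.0087). Chromosome 11 held 18 knockout-only and 36 wild-type-only regions (odds ratio 0.389, 0.217 to 0.699; adjusted p = 0.0319 by Fisher's exact test), and was the 1 chromosome of 20 past the threshold. Its members named here were the wild-type-only regions at Wipi1, Ttc25 and Spred2 and the knockout-only region near Cpeb4. Chromosomes 1, 3 and X held more knockout-only regions (41 against 20, 23 against 9 and 17 against 5) but did not pass after adjustment, each with adjusted p = 0.238 by Fisher's exact test. The chromosome difference did not pass at −log10 q of at least 5 in every library (permutation p = 0.168) or in both libraries of the calling genotype (permutation p = 0.0680).

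Peak number was 11564 ± 678 (SD, n = 2) in wild type and 11910 ± 755 (SD, n = 2) in knockout, a difference of 346 within the spread (exact permutation p = 0.667). The knockout library had 1359 more peaks than wild type at 1 h and a difference of −667 at 2 h. Median peak width was 443.5 ± 7.78 bp (SD, n = 2) in wild type and 410.5 ± 2.12 bp (SD, n = 2) in knockout, with both knockout libraries below both wild-type libraries (exact permutation p = 0.333).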

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

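The genotype difference in peak number went opposite ways at the labelled times: knockout minus wild type was 1359 peaks at 1 h and −667 peaks at 2 h. The covered length moved with it, by 388.8 kb at 1 h and −755.9 kb at 2 h. With 1 library per genotype and time, the difference between times was not tested. In the 1 h pair the wild-type library had the lower background (0.787 against 1.04 fragments per base), and in the 2 h pair the higher (1.08 against 1.01).

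Peaks on the mitochondrial chromosome, which entered no comparison, numbered 2 in each library.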

How the results depend on the processing

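The tests with long non-coding genes, equal-width windows and genes taken by span, and the limma comparison, shift test and list medians on pileups, were chosen after the data were seen; the others were planned. The gene-edge odds ratio stayed below 1 and past the threshold in all 12 alternatives run, from 0.290 to 0.758, and the Jaccard difference ranged from 0.0148 to 0.0191. With libraries left out it was 0.294 to 0.758; the classes then need 1 call in a genotype and 2 in the other, by construction. Peak number, knockout minus wild type, changed sign: −260.5 at −log10 q of at least 5, and −187.5 to 879.5 with libraries left out. Regions with −log10 q of at least 5 in the calling genotype numbered 151 (knockout-only) and 158 (wild-type-only), since that threshold is stricter; leaving out libraries gave 638 to 1651 and 617 to 1208, since fewer calls define a class. At −log10 q of at least 5 in every library 1 gene list test passed, against 0, and the chromosome p was 0.168; it was 0.0680 with the threshold on the calling genotype and 0.00435 to 0.0490 with libraries left out. The cut in every library also dropped weaker peaks of the other genotype, so regions called in both genotypes could enter a class. The cause of these changes was not otherwise tested. Shared regions differing in pileup by limma numbered 0 to 14 with libraries left out, with fewer samples. Of 47 named exclusive regions, 43 stayed in their class at equal list length and 33 under each stricter threshold. Of the 24 named from gene lists (1 also named for strength), 14 left under the stricter thresholds. The 24 named for strength all stayed, which followed from their choice as the strongest and shows no stability. Replicate numbers share a labelled time, and the labels do not say whether they share anything more. Over shared regions the 2 h minus 1 h differences of the genotypes correlated at r = 0.00241. The knockout minus wild-type differences of the time pairs correlated at r = 0.1625. Regions are not independent, and these values cannot show whether a batch was shared. With the replicate block the pileup count was 21: the 17 regions kept their calls and 4 were added. The peak difference was 346, which the block could not change, since each genotype has 1 library per labelled time. The odds ratio was 0.541, pooled over the time pairs by the Mantel-Haenszel method. It covered all regions called in 1 genotype and not the other at a labelled time, a wider set than the knockout-only and wild-type-only classes. Motif tests were not run. Total depth is unknown, which limits what a missing peak shows. The weakest 25% recurred in all 4 libraries in 44.1% and 30.7% of cases in wild-type replicates 1 and 2. In knockout replicates 1 and 2, with backgrounds of 1.04 and 1.01 fragments per base, it was 28.5% and 42.5%. Recurrence thus did not simply follow the background, and it fell as lists grew longer, from 11084 to 12443 peaks.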

Other observations

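The pileup comparison of shared regions, the test of a shift between gene-edge and other regions, and the list medians over shared regions were chosen after the data were seen; the remaining tests were planned before. Within 8704 of the 8705 regions called in all 4 libraries, those whose pileup was recovered in each, and assuming that the caller did not rescale pileups, recovered summit pileups differed between genotypes at 17 regions (limma, adjusted p below 0.05), 15 higher and 2 lower in the knockout libraries, and at 775 with an unadjusted p below 0.05. Splitting the libraries by labelled time gave 0 regions (295 unadjusted), and the crossed split gave 0 (267 unadjusted). The largest difference lay 46331 bp from Gabrg1 (chromosome 5, 70704383 to 70705050), with 9 and 12 fragments in wild type and 37 and 25 in knockout, a log2 difference of 1.54 ± 0.28 (SE; limma adjusted p = 0.00138). Irs2, an adaptor of insulin and cytokine receptors, followed with 11 and 16 against 33 and 36 fragments at chromosome 8, 11091772 to 11092708 (log2 difference 1.39 ± 0.26, limma adjusted p = 0.00153). That region lies 83311 bp from the gene end and the knockout-only region of Irs2 lies 75285 bp from it.

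Further regions higher in the knockout libraries were linked to Armc9, Shoc1, Phactr4, Iffo2, Olfr263, Vamp3, St8sia1, Sgpp2, Khdc1a, Bcl2l13, 4930432M17Rik and Add2, and 1 had no gene end within 100 kb. At Add2, the beta-adducin gene of the red cell membrane skeleton, a region inside the gene (chromosome 6, 86074732 to 86075299) had 18 and 15 fragments in wild type and 33 and 32 in knockout (log2 difference 1.02, limma adjusted p = 0.0344), while another region inside the gene was wild-type-only. The 2 lower regions lay 3088 bp from Lpar5, a lysophosphatidic acid receptor gene (42 and 42 against 23 and 13 fragments), and at the edge of Mfn1, a mitochondrial fusion gene (43 and 39 against 29 and 12). Of the 17, 3 were at a gene edge, against 68.4% of all regions called in all 4 libraries. No region passed without wild-type replicate 1 or without wild-type replicate 2 when 1 library stands for a genotype and is assumed to vary like the others. The pileups of the genotypes did not overlap at any of the 17 regions, so each kept its direction in these runs. Without knockout replicate 1, 5 passed (1 higher and 4 lower, 3 of them among the 17), and without knockout replicate 2, 14 passed (9 higher and 5 lower, 7 of them among the 17). The 10 gene lists with at least 5 shared regions showed no shift of their median pileup difference against 10000 random sets with the same number of gene-edge regions: 0 passed, and 0 had an unadjusted p below 0.05. The erythroid list, with 32 regions, had a median log2 difference of 0.03 where random sets spanned −0.07 to 0.13.

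The lower gene-edge share of knockout-only regions was weighed against 4 technical readings. Unequal list length is argued against, since the odds ratio was 0.327 with lists of equal length. With −log10 q of at least 5 in the calling genotype it was 0.290. The calling-genotype peaks closest to the threshold thus do not alone carry the difference. That cut still passed 9497 to 10788 peaks per library, and a peak missing in the other genotype may lie just below its threshold. A part played by weak peaks therefore stays open. Differences between single libraries stay open: the crossed split gave an odds ratio of 0.609, with an interval (0.393 to 0.942) that overlaps that of the genotype split (0.266 to 0.509). Shared regions moved in the same direction, with the median log2 pileup ratio of knockout over wild type lower at gene edges than elsewhere by −0.0855 (95% bootstrap interval −0.102 to −0.0637) at 1 h and −0.0804 (−0.101 to −0.0602) at 2 h, against −0.00752 and 0.00336 for 2 h over 1 h within wild type and knockout. The difference could therefore be part of a small shift over whole libraries. Such a shift may come from loss of Chd7, from the clone or from the GC or fragment make-up of the libraries. Median fold enrichment was also lower in knockout replicates 1 and 2 (7.59 and 7.46) than in wild-type replicates 1 and 2 (8.20 and 7.94). Neither GC content nor this difference in enrichment was tested as a source of the shift.

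The uneven spread over chromosomes was weighed against copy number and gene-edge share. On chromosome 11 the median log2 pileup ratio of shared regions departed from that of the genome by −0.0613 at 1 h and −0.0115 at 2 h, at most 0.0613 in size, which argues against a gain or loss of the whole chromosome; smaller segments were not tested. A permutation test within gene-edge and other regions separately still gave p = 0.00216, so the gene-edge share alone does not account for it. The same permutation test gave p = 0.520 for the split by labelled time and 0.481 for the crossed split, with 458 and 507 regions against 760. A tie to Chd7 loss was not tested. The difference did not pass under the stricter thresholds (permutation p = 0.168 and 0.0680). These left 670 and 309 regions, so a loss of power cannot be told apart from a loss of the pattern.

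The excess of exclusive regions in the genotype split over the next highest split was 1.499 times with all peaks and 1.64 times with lists of equal length. With −log10 q of at least 5 in the calling pair alone, a cut that most peaks passed, it was 1.58 times. It was 1.37 times when every library needed −log10 q of at least 5. Unequal list length thus does not account for all of the excess, and a part played by weak peaks stays open, since the ratio moved both ways under the stricter thresholds. As a hypothesis, the excess may reflect genotype or clone, which these libraries do not separate, and 3 splits are too few to exclude chance.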
